A study of Mus musculus with 6 samples.

How the data were processed

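RNA-seq was measured in 6 libraries of splenic naive B cells, 3 wild-type and 3 Zfp318 knockout, grouped by the genotype in the labels. Per the labels' protocols, about 200 cells per library were sorted into lysis buffer, reverse transcribed with an oligo-dT primer and a template-switching oligonucleotide, and amplified with 17 PCR cycles; no molecular identifiers are mentioned, so reads are not independent molecules. No strand marking is mentioned, so overlapping and antisense genes cannot be told apart. Per the submitters' processing notes, Trim Galore 0.6.6, STAR 2.2.0 and featureCounts were used with mm10; their parameters are not given in the sources used here.

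The authors deposited a table of normalized signal with 22680 rows and 6 columns, all of them used. The values are read numbers per gene divided by a factor per library. By the name the authors gave them, the reads were counted over coding sequence (CDS), so reads in untranslated regions would not be included. Dividing by the smallest step in each column gave whole reads for 100% of the values (tolerance 0.001), with library factors between 4.51 and 6.09. How the factors were computed is not given in the sources used here. The recovered reads totalled 5959100 to 8192565 per library, and the totals of the 2 genotypes overlapped. Rows at 0 in all libraries numbered 9217, and 27 rows carried names turned into dates by a spreadsheet; these rows were kept but never named. Gene positions, exon numbers and coding GC content came from the GENCODE annotation of the mm10 assembly, matched by symbol for 20140 rows (88.8%). A coding GC value was found for 95.9% of the genes tested.

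The main test was limma 3.58.1 (R 4.3.3; lmFit and eBayes with a mean-variance trend, two-sided) on log2(value + 1) with genotype as the only term, over genes with a mean of at least 10 over the 6 libraries, and Benjamini-Hochberg adjustment over the 7751 genes tested; genes were called at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Gene lists, 36 in all, of which 31 had at least 5 tested members, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Single values were compared with exact two-sided permutation tests, for which 3 against 3 libraries cannot go below p = 0.1. Before averaging, the libraries of a group were compared: every pair differed by more than the sampling of independent reads would give (mean chi-square per gene from 11.3 to 19.2 within groups). As the reads are not independent molecules, this does not show a spread beyond the sampling of molecules or cells.

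The gene lists, tests, alternatives and rule for named genes were fixed before the data were examined. The rule took Zfp318, Ighd and Ighm; the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, without variable segments and unnamed gene models; in each list up to 4 tested members with the smallest p and any other called member; and for lists of other cell types and the sex chromosome genes the member with the highest mean. A part of the genes it takes is named here. The lists cover B cell subsets and receptor signalling, immunoglobulin genes, mitochondrial function and metabolism, ribosomal proteins, stress, activation and cell cycle, and markers of other spleen cells.

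Alternatives were pseudocounts of 0.5 and 5, no filter and a minimum mean of 50, 3 rescalings, limma without the trend or with array weights, the replicate number as a block, leaving out each library, edgeR 4.0.16 (quasi-likelihood with TMM) and DESeq2 1.42.0 on the recovered reads. Added after seeing the data were the removal of each library's trend with coding GC content (local regression, span 0.4), the same with coding length, and a fit without wild-type 1 and knockout 2. The steps were tested on simulated data: reads drawn for the 7751 genes with 200 genes changed. A further set of genes was raised by 0.3 on the log2 scale and left out of the shares given next. For the comparison of knockout with wild type, limma recovered 20% of genes changed 1.5-fold, 54% of those changed 2-fold, 96% of those changed 4-fold and 100% of those changed 8-fold, and called 0.134% of unchanged genes. Changes under 2-fold are therefore often missed at this depth and number of libraries. These simulated genes were drawn independently and without a trend with GC content, so the share of unchanged genes called may differ here.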

Results

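The series measured polyadenylated RNA in naive B cells sorted from the spleens of wild-type mice and of mice lacking Zfp318, a zinc finger protein of the nucleus that mature B cells need in order to express IgD. The sort took cells positive for B220 and IgM and negative for CD138, GL7 and FAS, markers of plasma cells and of germinal centre cells. About 200 cells went into each library, and their cDNA was amplified with 17 PCR cycles. There were 3 wild-type and 3 knockout libraries. The reads counted over coding sequence numbered 6450898, 7784826 and 8156842 in wild-type libraries 1 to 3, and 5959100, 8192565 and 7419836 in knockout libraries 1 to 3. The labels speak of a single mouse per experiment and do not say whether the 3 libraries of a genotype came from 3 mice, so the p-values below measure the spread between these libraries, which may be technical. The question put by the design is how the transcriptome of naive B cells differs without Zfp318.

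The targeted gene was examined first. Zfp318 (chromosome 17, 46383731 to 46420920, plus strand, mm10) had normalised values of 122, 97.2 and 67.0 in the wild-type libraries and of 16.0, 11.5 and 22.8 in the knockout libraries. Its mean was 95.4 ± 27.6 (SD, n = 3) in wild type and 16.7 ± 5.68 (SD, n = 3) in knockout. The log2 fold change was -2.45 (SE 0.27, limma adjusted p = 2.17e-04), and the exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. All 6 libraries thus had Zfp318 on the side their label gives. The call was lost without the mean-variance trend in limma (adjusted p = 0.0529). Reads remained in the knockout. The labels write the knockout genotype as homozygous for an allele called ZSDAT, which they do not explain, and do not say which part of the gene was altered or whether the allele changes anything else.

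Ighd, which encodes the constant region of the IgD heavy chain, had the largest fall among the genes called and kept 11.5% of its wild-type mean. It lies on chromosome 12 (113406604 to 113416324, minus strand), 2234 bases downstream of Ighm (113418558 to 113422730), from which it is expressed by alternative processing of a shared transcript. Ighd fell from 895 ± 141 to 103 ± 19.5 (SD, n = 3 each), a log2 fold change of -3.12 (SE 0.14, limma adjusted p = 7.81e-09, exact permutation p = 0.1). Ighm, the constant region of the IgM heavy chain, had 25790 ± 3073 in wild type and 22683 ± 1068 in knockout (SD, n = 3 each). Its log2 fold change of -0.18 (SE 0.08) did not pass the test (limma adjusted p = 0.283, exact permutation p = 0.2).

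**Figure D1:**
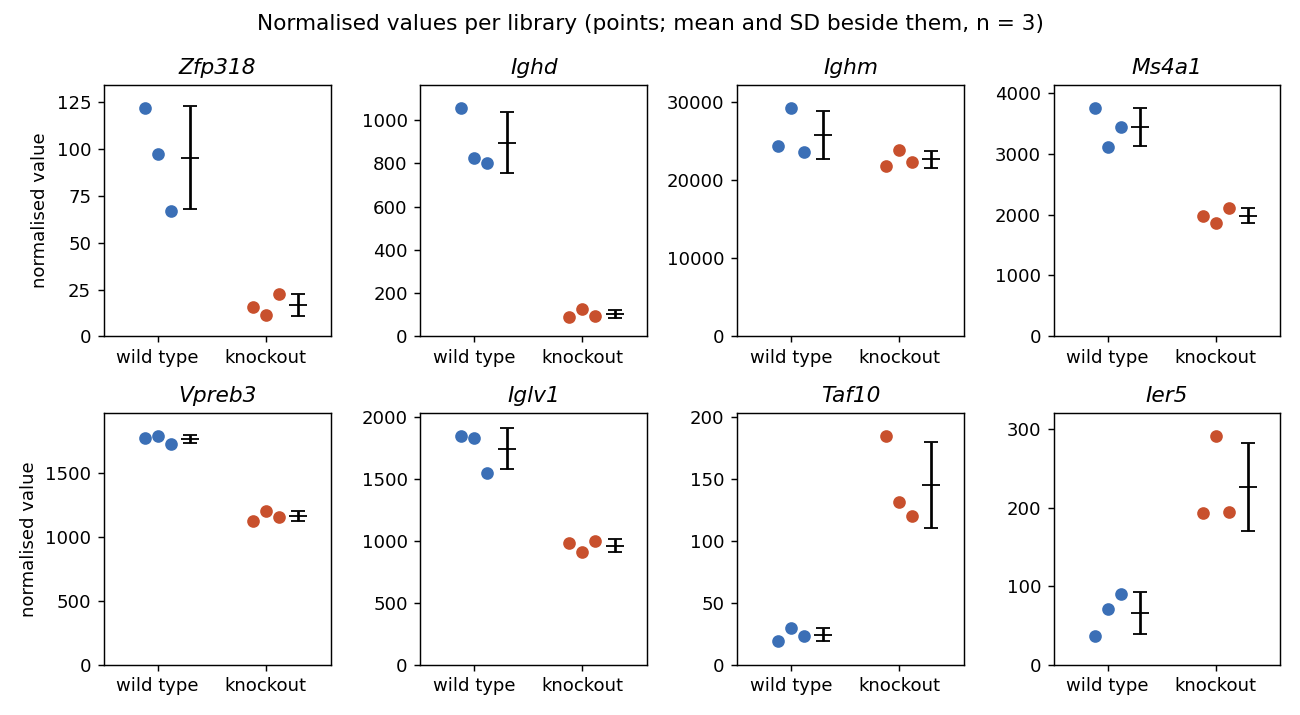
Normalised values (vertical axis, linear, starting at 0) of 8 genes in each of the 3 wild-type and 3 knockout libraries, with the mean and SD of each group beside the points. Ighd fell from 895 to 103, and the groups of Ighm overlapped.

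Across the transcriptome, 130 of 7751 genes tested differed between the genotypes (limma, Benjamini-Hochberg adjusted p under 0.05), 81 higher and 49 lower in the knockout. Variable segments and unnamed gene models left aside, the largest rises were in Rnf187, an E3 ubiquitin ligase (19.8 ± 8.60 to 137 ± 26.4, log2 fold change 2.81, SE 0.29), and in Taf10, a subunit of the general transcription factor TFIID (24.1 ± 5.20 to 145 ± 34.6, log2 fold change 2.54, SE 0.21; SD, n = 3 each). Fam101b (2.25), Fbrsl1 (2.204), the RNA exosome subunit Exosc6 (2.05), the store-operated calcium channel Orai1 (1.94), the mitochondrial magnesium channel Mrs2 (1.93), Ccny (1.87), the immediate early gene Ier5 (1.84) and Bloc1s4 (1.84) followed, in log2 fold change. Exosc6, Ier5 and Bloc1s4 have 1 annotated exon, and their coding sequences are rich in GC (75.2%, 71.9% and 71.5%). After removal of each library's trend with coding GC content, a correction chosen after seeing the data, their log2 fold changes were 1.26, 1.22 and 1.23, and all 3 were still called. Rnf187 (67.9%), Fbrsl1 (65.8%), Taf10 (64.7%) and Orai1 (63.3%) also lay in the top decile of coding GC content, which starts at 59.6%. Their log2 fold changes after the removal were 2.38, 1.87, 2.25 and 1.71, and all of them were still called. Mrs2 (53.5%) and Ccny (49.5%) lay outside that decile, and Fam101b had no GC value. Below Ighd and Zfp318, and again without variable segments and unnamed gene models, the largest falls were in Agbl1, a carboxypeptidase gene (32.8 ± 2.16 to 7.95 ± 1.58, log2 fold change -1.93), Gh, the growth hormone gene (-1.40), Slamf9 (-1.22), Cdk5rap1 (-1.21), the MAP kinase phosphatase Dusp10 (-1.15), the histone deacetylase Hdac9 (-1.06), Eaf2 (-1.04) and Hsdl2 (-1.02). Gh lies 9476 bases downstream of Cd79b on the same strand of chromosome 11.

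Immunoglobulin variable segments made up 11 of the calls, 10 of them lower, and gene models without a proper name made up 6. In all 130 genes the 3 knockout values lay on 1 side of the 3 wild-type values, as they did for 21.9% of the genes tested. Chance gives 10% on average over the possible splits of the libraries. Genes that vary together can put a single split well away from this average, and the shares in the other splits were not measured. A fold change of at least 2 in size (1 on the log2 scale) was reached by 63 of the calls. With the libraries rescaled by the median of ratios, 148 genes were called, 111 higher and 37 lower. Without the mean-variance trend limma called 5 genes, and DESeq2 on the recovered reads called 353. Leaving out wild-type 1 left 54 calls, and leaving out knockout 1, 2 or 3 left 42, 56 or 71. Among the genes named above, Zfp318, Ighd, Rnf187, Taf10, Fbrsl1, Exosc6, Orai1, Ier5, Agbl1 and Dusp10 were called in all 6 fits that left out a library; 31 of the 130 genes were. Ccny was called in 5 of these fits, Bloc1s4 in 4, Hdac9 in 3, Gh in 2, Fam101b, Mrs2, Slamf9 and Cdk5rap1 in 1, and Eaf2 and Hsdl2 in none.

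**Figure D2:**
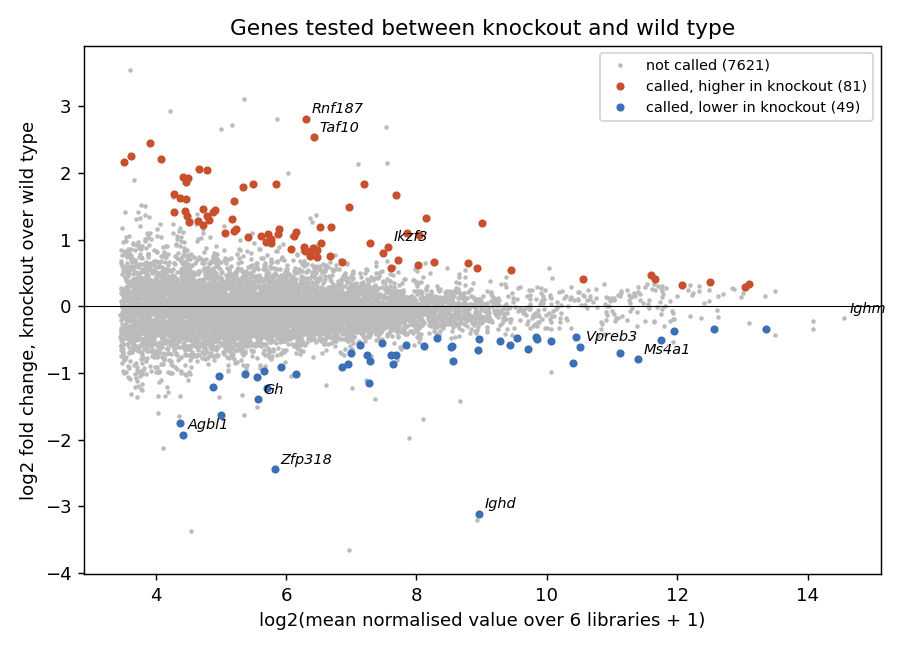
Log2 fold change of knockout over wild type (vertical axis) against the log2 of the mean normalised value plus 1 (horizontal axis) for 7751 genes, a point per gene. The 81 genes called higher and the 49 called lower are coloured; among the called genes Ighd and Zfp318 lie lowest, at -3.12 and -2.45.

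Several genes of mature and immature B cells moved. Ms4a1, which encodes the surface antigen CD20, fell from 3436 ± 319 to 1981 ± 123 (SD, n = 3 each; log2 fold change -0.79, SE 0.09, limma adjusted p = 2.17e-04). Ikzf3, which encodes the transcription factor Aiolos, rose by 0.90 on the log2 scale (adjusted p = 4.93e-03). These were the only calls among 24 tested members of the follicular B cell identity list, of which 6 passed when adjusted over the list alone, 5 higher and 1 lower. In the transitional and immature B cell list, Vpreb3 fell by 0.60 and Cd24a fell by 0.59 (log2), and the other 5 tested members did not pass. The list as a whole was lower (median log2 fold change -0.20, camera adjusted p = 0.0219; adjusted p = 0.351 with an estimated correlation); 2 members passed when adjusted over the list alone. That call was lost without the limma trend (adjusted p = 0.140), with edgeR on the recovered reads (0.0518), without wild-type 2 (0.0819) and without knockout 2 (0.0876). The median of this list was -0.35 without wild-type 1, -0.48 without knockout 3, and -0.09 in both edgeR and DESeq2. Of 30 B cell receptor signalling genes, Cd79a and Cd79b, the signalling chains of the receptor, each fell by 0.34, and 7 members passed when adjusted over the list alone, 2 higher and 5 lower; the list was not called (camera adjusted p = 0.107). A removal of each library's trend with coding GC content, a correction chosen after seeing the data, left Cd79a at -0.32 and Cd79b at -0.30. Neither passed then (limma adjusted p = 0.101 and 0.118), although their fold changes were little smaller. Each was called in 1 of the 6 fits that left out a library. Of 15 marginal zone B cell genes, Cd36, a scavenger receptor, fell by 0.82 and was the only call, also when adjusted over the list alone (camera adjusted p of the list = 0.944).

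Of 155 immunoglobulin variable segments tested, 10 fell and 1 rose, 35 had a positive and 120 a negative fold change, and 30 passed when adjusted over the list alone, 29 of them lower. The list was called lower (median log2 fold change -0.43, camera adjusted p = 3.28e-07; adjusted p = 0.351 with an estimated correlation). Its median was -0.24 after removal of the trends with coding GC and length, a correction chosen after seeing the data. The lambda segments Iglv1 (-0.85) and Iglv3 (-0.82) and the kappa segment Igkv16-104 (-0.91) fell, and the kappa segment Igkv3-1 (2.44), with values from 0.68 to 32.1, rose. Igkv3-1 was called in 1 of the 6 fits that left out a library. Reads of near-identical segments may be shared out by the counting, so single segments are uncertain. Of 5 heavy chain constant genes tested, only Ighd was called, also when adjusted over the list alone; the list was called lower (camera adjusted p = 6.25e-03; adjusted p = 0.351 with an estimated correlation), and that call was lost with no filter (adjusted p = 0.0507), without the limma trend (0.0621) and without knockout 2 (0.0567). The median of this list went from -0.36 to -0.22 without wild-type 1, -0.24 without wild-type 3 and -0.18 with no filter. Plasma cell genes were not called as a list (12 tested, camera adjusted p = 0.604, 1 lower when adjusted over the list alone); Jchain, the joining chain of secreted IgM, had values of 220, 798 and 244 in wild type and 123, 46.8 and 214 in knockout. Immunoglobulin genes took 5.66% ± 0.71 of the total in wild type and 4.52% ± 0.15 in knockout (SD, n = 3 each; exact permutation p = 0.1, the smallest possible).

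Transcripts of cytosolic ribosomal proteins were higher as a group. Of 80 tested, 7 rose and none fell, 73 had a positive fold change, and 26 passed when adjusted over the list alone, all higher. Rps2 (0.48), Rpl36 (0.41), Rps27 (0.33) and Rpl8 (0.32) were among the calls, in log2 fold change. Of the 6 fits that left out a library, Rps2 was called in 2 and each of the other 3 in 1. The list was called higher (median 0.17, camera adjusted p = 2.81e-21; adjusted p = 0.745 with an estimated correlation). Its median was 0.26 after removal of the trends with coding GC and length. Ribosomal protein genes took 17.0% ± 1.19 of the total in wild type and 20.0% ± 1.29 in knockout (SD, n = 3 each; exact permutation p = 0.1, the smallest possible).

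Of the mitochondrial gene lists, 2 were called lower. All 10 tested genes encoded by mitochondrial DNA had negative fold changes; mt-Cytb, a subunit of complex III, fell by 0.50 (log2; called in 1 of the 6 fits that left out a library), while mt-Co1 (-0.53) and mt-Nd2 (-0.59) did not pass. The list was called lower (median -0.43, camera adjusted p = 1.29e-04; adjusted p = 0.791 with an estimated correlation), and 6 members passed when adjusted over the list alone. The list was no longer called after removal of the GC trend (median -0.08, adjusted p = 0.196). These genes took 1.07% ± 0.25 of the total in wild type and 0.769% ± 0.064 in knockout (SD, n = 3 each; exact permutation p = 0.2). Wild-type libraries 1 to 3 had 1.32%, 1.07% and 0.828%, and knockout libraries 1 to 3 had 0.711%, 0.837% and 0.758%. The difference thus rests in good part on wild-type 1. Among the nuclear-encoded lists of mitochondrial function, the tricarboxylic acid cycle list was lower (22 tested, none called, also when adjusted over the list alone; median -0.15, camera adjusted p = 0.0410, adjusted p = 0.791 with an estimated correlation); Idh3a, a subunit of isocitrate dehydrogenase, had -0.46 and did not pass. This list was not called after removal of the GC trend (adjusted p = 0.127), nor without wild-type 1 (0.0812), wild-type 3 (0.116), knockout 1 (0.0768) or knockout 2 (0.0594). Nor was it called with the stricter filter (0.0856), rescaling to the same total (0.0609), the median-of-ratios rescaling (0.0951), immunoglobulin and mitochondrial genes removed (0.05002), no limma trend (0.0956), array weights (0.0578), edgeR (0.150) or DESeq2 (0.129). Its median was -0.07 after the GC correction and -0.09 with the median-of-ratios rescaling, edgeR or DESeq2.

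Respiratory complex I (35 tested, camera adjusted p = 0.944), complexes II to IV (24 tested, 0.944), ATP synthase (15 tested, 0.944), mitochondrial ribosomal proteins (74 tested, 0.944), biogenesis and DNA maintenance (21 tested, 0.989), fatty acid oxidation (19 tested, 0.944), antioxidant defence (18 tested, 0.591), mitochondrial stress (11 tested, 0.905) and glycolysis (13 tested, 0.457) held no called gene and were not called; none of their members passed when adjusted over the list alone. In the list of mitochondrial dynamics, import and mitophagy (30 tested, camera adjusted p = 0.944), Pink1, the kinase that marks damaged mitochondria for mitophagy, rose by 1.12 (limma adjusted p = 4.94e-03) and was the only call, also when adjusted over the list alone. Pink1 was called in all 6 fits that left out a library.

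Immediate early and activation genes were higher as a list (22 tested, 3 called, 5 when adjusted over the list alone; median log2 fold change 0.21, camera adjusted p = 1.10e-04; adjusted p = 0.745 with an estimated correlation). Ier5 (1.84), Jun (1.69) and Ier2 (0.80) rose, and Junb (0.57) did not pass. After removal of the GC trend Ier2 had 0.52 and did not pass (limma adjusted p = 0.0731). Of the 6 fits that left out a library, Ier5 was called in 6, Ier2 in 2 and Jun in 1. The list was called in all of them, with a median of 0.09 without wild-type 2 and 0.33 without wild-type 3. The heat shock and tissue handling list, which shares Jun, was not called (13 tested, camera adjusted p = 0.944, 2 passing when adjusted over the list alone), and its member Dnaja1, a heat shock co-chaperone, had -0.42. The lists of cell cycle genes (27 tested, camera adjusted p = 0.107), the BCL2 family (14 tested, 0.944), the type I interferon response (18 tested, 0.944), transcription termination and RNA processing (24 tested, 0.591), B-1 cells (6 tested, 0.944) and memory B cells (11 tested, 0.944) were not called and held no called gene. Bcl2 (0.67) and Irf7 (0.63), the latter an interferon regulatory factor, had adjusted p of 0.0965 and 0.0654 in limma; each was the 1 member of its list that passed when adjusted over the list alone, and none passed in the other 4 lists.

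Most markers of T, NK and dendritic cells lay under the minimum mean of 10 (2 of 16, 1 of 11 and 2 of 12 were tested). Some markers of other cells were high, in all libraries or in a part of them. The complement genes C1qc (20.1 ± 9.58 to 67.7 ± 6.11, log2 fold change 1.83) and C1qb (1.16), made by macrophages, rose (SD, n = 3 each; called in 5 and 2 of the 6 fits that left out a library), while Vcam1 (1.298) and Fcer1g (0.85) did not pass. The monocyte and macrophage list was higher (12 tested, 2 called, 6 when adjusted over the list alone; median 0.53, camera adjusted p = 2.68e-03; adjusted p = 0.351 with an estimated correlation); Ctss, its most abundant member, which B cells also express, had a log2 fold change of 0.07. The median of that list was 0.22 with no filter and 0.32 without knockout 2. With a minimum mean of 50 it had a median of -0.19 and was not called (adjusted p = 0.656), nor was it without wild-type 1 and knockout 2, a pair left out after seeing the data (adjusted p = 0.110). Haemoglobin Hba-a1 had values of 2.96, 30.6 and 105 in wild type and 347, 632 and 4.20 in knockout. The neutrophil granule genes Ngp, Ltf and Camp had 210, 187 and 344 in knockout 2. They were listed at 0 in the 3 wild-type libraries and knockout 1, and at no more than 0.35 in knockout 3. S100a9 had 467 in knockout 2, 54.3 in wild-type 2 and no more than 1.05 in any other library. The erythroid and platelet list (5 tested, camera adjusted p = 0.0838) and the neutrophil list (5 tested, 0.0683) were not called. The T cell, NK cell, dendritic cell and germinal centre lists and the sex chromosome genes had fewer than 5 tested members and no list test; among them Eaf2 and Ddx3y (-0.92; called in 2 of the 6 fits that left out a library) were called lower, Lck (0.19), Ccl5 (-0.89), Tcf4 (0.30) and Eif2s3y (-0.43) were not, and 1 germinal centre and 2 sex chromosome members passed when adjusted over the list alone.

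With fry tested for direction, the heavy chain constant genes were the only 1 of the 8 called lists to pass (adjusted p = 3.17e-03). That list has 5 tested members and holds Ighd, its only called gene, so it adds little to the fall of Ighd. The antioxidant defence list, not called by camera, passed as lower (adjusted p = 0.0229).

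**Figure D3:**
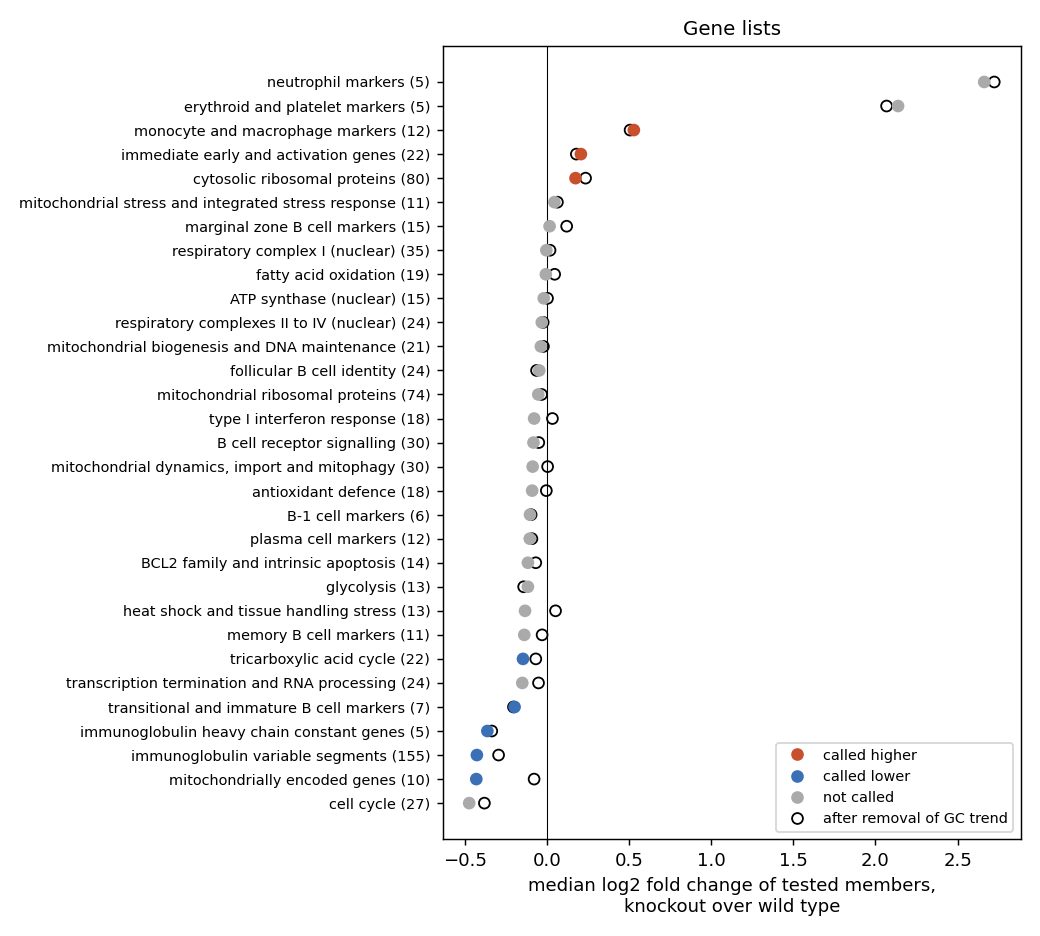
Median log2 fold change of knockout over wild type (horizontal axis) of the 31 tested gene lists, with the number of tested members in brackets. Filled points show the fit as planned, coloured where camera called the list, and open circles the medians after removal of each library's GC trend; the median of mitochondrially encoded genes moves from -0.43 to -0.08.

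The libraries also differed in how their values followed GC content, and this difference ran along the genotypes. The median deviation of genes in the top decile of coding GC content minus that in the bottom decile was -0.42, -0.25 and 0.06 (log2) in wild-type libraries 1 to 3 and 0.24, 0.26 and 0.13 in knockout libraries 1 to 3 (exact permutation p = 0.1, the smallest possible). The median log2 fold change was -0.23 in the bottom decile and 0.17 in the top decile, and 30 of the 81 genes called higher lay in the top decile. After removal of the trend 121 of 7436 genes were called, 78 higher and 43 lower, and 84 of the 124 planned calls with a GC value were among them. The same genes without the correction gave 107 calls. Of the genes named, Taf10, Rnf187, Orai1, Ikzf3, Ms4a1, Vpreb3, Iglv1, Pink1, C1qc, Zfp318 and Ighd were called after the correction, and Cdk5rap1, Eaf2, Hsdl2, Rpl36, Rps2, Rpl8, mt-Cytb and Ddx3y were not. In log2 fold change, Cdk5rap1 went from -1.21 to -1.13, Eaf2 from -1.04 to -0.87 and Hsdl2 from -1.02 to -0.87. Rps2 went from 0.48 to 0.43, Rpl36 from 0.41 to 0.24 and Rpl8 from 0.32 to 0.24. The fall of mt-Cytb went from -0.50 to -0.19, and that of Ddx3y from -0.92 to -0.70.

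**Figure D4:**
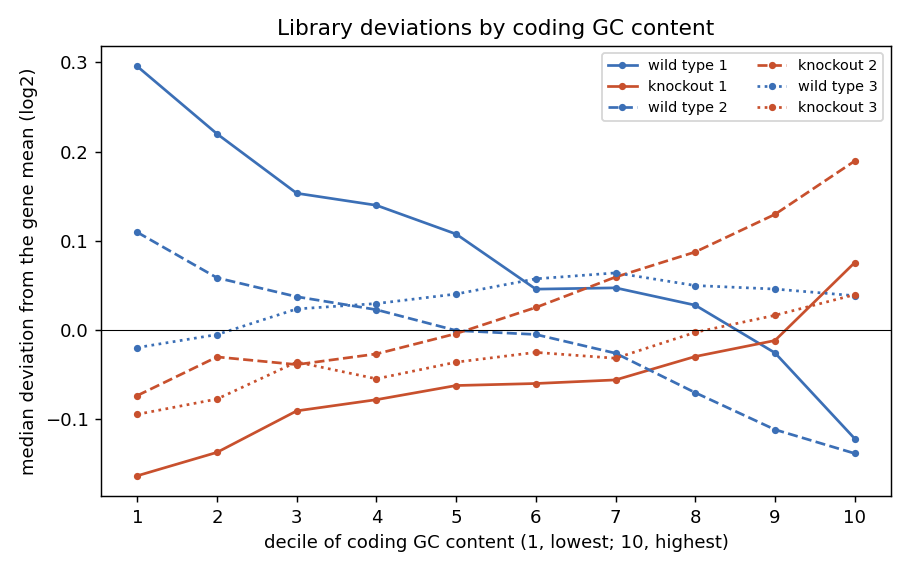
Median deviation of each library from the gene means (vertical axis, log2) in 10 bins of coding GC content (horizontal axis), a line per library. The top bin minus the bottom bin was negative in wild-type libraries 1 and 2 and positive in wild-type 3 (0.06) and the 3 knockout libraries.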

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

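The GC and length corrections and the fit on 4 libraries were chosen after seeing the data. The 130 genes called became 65 with no filter, 71 with the stricter filter, 199 with immunoglobulin and mitochondrial genes removed, 5 without the limma trend, 353 with DESeq2, 42 without wild-type 1 and knockout 2, 293 at an adjusted p under 0.1, and 63 with a log2 fold change of at least 1 in size; leaving out a library gave 42 (without knockout 1) to 123 (without wild-type 2). Fewer samples account for part of the latter; the cause was otherwise not tested. Both pseudocounts, the other rescalings, array weights, edgeR (125 called, 102 of them among the 130) and the GC corrections stayed within 1.5 times. In each alternative the called genes it tested kept their sign. The groups overlap in none of the 130 genes. Leaving out libraries or changing the pseudocount, filter, trend, weights or block could therefore not turn a sign. Only the rescalings, the GC corrections, edgeR and DESeq2 could have done so. With the replicate number as a block, 95 genes and 10 lists were called. Same-numbered libraries did not deviate together (correlations -0.02, 0.04 and 0.01), so no shared effect of the number was seen. Whether the numbers pair the mice or the preparation is not in the labels, and these correlations cannot tell.

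The 8 called lists became 4 with the stricter filter, 4 with immunoglobulin and mitochondrial genes removed, 5 without the trend, 0 with an estimated correlation, 2 with fry tested for direction and 22 with fry tested for change in either direction; leaving out a library gave 5 to 10. Zfp318 kept -2.45 without the trend but did not pass (adjusted p = 0.0529); without a library it lay between -2.69 and -2.22, and Ighd between -3.26 and -2.99, both called each time. The knockout minus wild-type share, in percentage points, lay between -0.42 and -0.18 for mitochondrially encoded genes, 2.28 and 3.65 for ribosomal protein genes and -1.48 and -0.77 for immunoglobulin genes without a library. None of the called genes named reversed in an alternative run, which the lack of overlap between their groups fixed in advance for most alternatives. S100a9, not called, lay between -1.41 (without knockout 2) and 3.30 (without wild-type 2). Without wild-type 1 and knockout 2, S100a9 (-2.38), Hba-a1 (-0.44) and Hbb-bs (-0.16) turned negative. Without knockout 3, Hba-a1 (4.31, limma adjusted p = 0.0198) and Hbb-bs (4.99, limma adjusted p = 0.0193) were called higher. The cause was not tested. Lgmn, at -0.04 and not called, lay between -0.092 (without wild-type 2) and 0.018 (without knockout 3) and just above 0 with the median-of-ratios rescaling (0.0236), edgeR (0.0258), DESeq2 (0.0262), the GC correction (0.0177), the GC and length correction (0.0245), and without wild-type 1 and knockout 2 (0.0111).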

Other observations

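The tests of other splits, the GC trend, the region around Zfp318, macrophage RNA and the share of B cells were written down after the results they measure were seen; those of transcript length and of downstream genes were written before. Beyond the genes described above, 3 further genes, named after their values were seen, rose in the knockout: Ybx1, an RNA-binding protein (168 to 355, log2 fold change 1.07, limma adjusted p = 2.21e-03), Hnrnpab (1.33) and the spermidine synthase Srm (0.94), each called in all 6 fits that left out a library. The lambda constant gene Iglc1 fell from 2773 to 1709 (-0.69, limma adjusted p = 9.12e-04), while Iglc2 (-0.29), Iglc3 (-0.21) and the kappa constant gene Igkc (-0.34) did not pass. In wild-type 2, the library with the most Jchain (798), a heavy and a kappa variable segment stood out: Ighv1-34 had 720, against 6.75 and 12.5 in the other wild-type libraries, and Igkv1-122 had 2716, against 83.0 and 59.6. Knockout libraries had 1.99, 0.985 and 5.25 of Ighv1-34 and 25.0, 24.3 and 25.2 of Igkv1-122, and neither segment was called. Without wild-type 2 the variable segment list was still called lower (median log2 fold change -0.45, camera adjusted p = 1.70e-07). The pancreatic protease genes Ctrb1 (3.10, 5.58 and 58.2 in knockout 1 to 3, 0 in wild type) and Cela2a (13.3, 2.63 and 86.0, at most 1.48 in wild type) were not called either.

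The real grouping of the 6 libraries gave 130 called genes, and the highest of the other 9 gave 4; the real split was the 1 of 10 that reached this count, and 10 splits are too few for a share under 0.05. Of 124 called genes with a GC value, 84 passed after removal of the GC trend, which argues against each library's average trend as the whole cause of the calls. The removal takes out only the average over genes of like GC content. A stronger effect on single GC-rich transcripts would stay in the values. In the top GC decile lay 30 of the 81 genes called higher and 1 of the 49 called lower. The count therefore does not decide whether GC content acted on single genes. Within 5 Mb of Zfp318, itself left out, 0 of 44 tested genes were called, with a median log2 fold change of -0.01. As 1.68% of all genes tested were called, few or no calls among 44 genes would be found without any regional change. Changes carried in this region were thus not seen, but the count cannot exclude them. For the mitochondrially encoded genes the GC trend is a candidate cause: 68 nuclear genes in the same GC range (34.3% to 40.0%) had a median log2 fold change of -0.38, and the list went from -0.43 (SD 0.25 over genes) to -0.08 (SD 0.23) when the trend was removed. The ribosomal proteins behaved otherwise: their median was 0.23 after the GC correction, against 0.17 before it. A median of -0.0407 was found for 71 other genes with transcripts of 390 to 1943 bases and a mean of at least 944. These limits hold most ribosomal protein genes, but the 71 genes were not matched to them within the limits or on GC content. A difference in the cells or in another feature of the ribosomal protein transcripts stays open.

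C1q transcripts were higher in the knockout, and RNA from splenic macrophages may have contributed, although the sort for B220 should remove such cells. The sum of 14 macrophage genes outside the fixed list, of which Apoe (566 to 827) and Lgmn (358 to 349) were the most abundant, was higher by a log2 ratio of 0.38, less than C1q itself (1.19). Of the 14 genes 9 had a higher mean in the knockout, and 2 were called higher: Apoe (log2 fold change 0.54, limma adjusted p = 0.0161), in 3 of the 6 fits that left out a library and not after the GC correction (adjusted p = 0.171), and Fcna (22.4, 16.4 and 18.7 in wild type; 63.6, 58.1 and 30.8 in knockout), in 1 of those fits. B cells could also express Apoe and Lgmn, which make up most of the sum, so this does not decide it. A lower share of B cells in the knockout sorts would raise T cell transcripts in all 3 knockout libraries if T cells took their place. The sum of T cell transcripts was 93.9, 103 and 101 in wild type and 189, 96.5 and 120 in knockout. Without Lck, which B cells can express, it was 40.1, 60.3 and 47.3 against 126, 40.5 and 67.8. The log2 ratio of summed C1q to this sum did not overlap between the groups with Lck (-0.52, 0.17 and -0.37; 0.22, 1.13 and 0.43) and overlapped without it, where it was 0.71 to 0.94 in wild type and 0.81, 2.38 and 1.25 in knockout. Knockout 2 lacks the rise in T cell transcripts, but 1 library with so few T cell reads excludes nothing. Cells other than T cells could also take the place of B cells. Summed neutrophil markers were 3.17, 96.7 and 0 in wild type and 2.22, 1663 and 4.55 in knockout. Summed NK cell markers were 11.4, 25.4 and 26.4 against 20.6, 12.6 and 95.6. Summed dendritic cell markers, mostly Bst2 and Tcf4, were 268, 254 and 288 against 316, 356 and 290. A lower share of B cells thus stays open.

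Gh fell together with Ighd, and both lie just downstream of a strongly expressed gene on the same strand, which made less transcription past the 3' ends of such genes a possible explanation. Among tested genes, 46 others start within 20 kb downstream of a same-strand gene with a mean of at least 500 and 20 times their own level. Their median log2 fold change was 0.05, at percentile 96.2 of 10000 random lists matched on mean level, where a general loss of such transcription predicts a low percentile; 0 were called lower and 1 higher. No general fall of such genes was therefore seen. The random lists were not matched on GC content, and the 46 genes include mt-Co2, mt-Co3 and mt-Atp6, encoded by mitochondrial DNA. How much of the reads of these genes came from such transcription, rather than from their own, is not known. The values thus do not decide whether such transcription was lower, and what lowers Gh stays open.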
